A study of Homo sapiens with 6 samples.

How the data were processed

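Total RNA was extracted from 6 cell lines with Tri reagent and treated with DNase, and libraries were made with the PrepX mRNA Library kit on an Apollo 324 instrument, per the labels' protocols. Reads were single-end, per the series design text. The submitters' processing notes name CASAVA 1.8, RSEM without a version and the genome build hg19, with no role or order. The aligner's settings, the annotation and any filter were not given in the sources used here. Growth medium differed between lines per the labels, with added growth factor for UACC-812 and insulin for MDA-MB-415, and fetal bovine serum was 20% for UACC-812, SKBR3 and MDA-MB-453, 15% for MDA-MB-415 and 10% for T47D and CAL51, so culture conditions and line cannot be told apart. The labels give no sequencing batch.

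The deposited table gives, for each gene and line, a value read here as RPKM summed over the exons of the gene by the authors. No label states this unit. It was inferred from the deposited values, because low values of single-exon genes were whole-number multiples of 1 constant per library divided by the gene's length, and genes that share exons repeated the same values. A sum over exons grows with the number of exons, so levels of different genes are not set against each other, only levels of 1 gene between lines. Levels of different genes enter only where gene lists are matched or averaged and where genes are filtered by level. The number of exons affects those steps. With the recovered constant, 38.6% of single-exon genes with low values were whole within 0.01 reads in UACC-812, 37.4% in MDA-MB-415, 37.1% in SKBR3, 33.3% in MDA-MB-453, 35.0% in T47D and 35.3% in CAL51, against medians of 1.20% to 1.91% over other constants. Where constants fitted equally well the largest was taken, since its whole multiples also fit smaller constants that divide it. The constant so chosen gives the depth of each library. Because most genes have several exons, whole reads per gene could not be recovered, and no count model was used. A value of 3 reads in a 150 bp exon was worth 0.781 in UACC-812, 0.663 in MDA-MB-415, 0.593 in SKBR3, 0.589 in MDA-MB-453, 0.685 in T47D and 0.548 in CAL51. An exact 0 may be a gene with no reads or a value not estimated, so such genes are given as listed at 0, with no fold.

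The table held 16444 genes, all of which reached 1 in at least 1 line. Left out were 22 genes whose names a spreadsheet had turned into dates and 4 entries that shared 2 names, leaving 16418. Of the genes with values above 0 in 3 or more lines, 27 had the same values in all 6 lines, to 5 decimals, as a second gene, among them 7 of 9 UGT1A genes, and genes with shared exons or near-identical copies were treated as uncertain. Names matched a reference symbol for 15968 genes, and 15844 (96.5%) had a genomic span. The reference annotation is of a later build than hg19, so it was used for spans, exon numbers and the order of genes, and no coordinates are given.

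Values were compared as deposited on the log2(value + 1) scale, which understates the change of low genes. The deviation of a gene in a line is its log2 value minus the median of the 5 other lines. A gene was apart when it lay at least 2 log2 units beyond the nearest other line. The lists were interferon response, interferon and JAK-STAT receptors and kinases, MHC class I and class II antigen presentation, TNF and NF-kB inflammatory response, innate sensing, death receptor pathway, checkpoint and natural killer ligands, TGF-beta, RNA polymerase II elongation, splicing, chromatin regulators, histones, estrogen receptor, luminal, basal, mesenchymal, 17q12, ERBB receptors and ligands, proliferation, p53 targets, ribosomal proteins, oxidative phosphorylation, glycolysis, cholesterol synthesis, unfolded protein response, cancer-testis antigens, leukocyte markers, stromal markers and genes of other tissues. Each list's median deviation was placed among 10000 random lists matched on mean expression in 20 bins. The groups, comparisons, lists, named-gene rule, thresholds and all alternatives except those given next were fixed before the data were examined. Short lists of the authors, found in the deposited workbook (11 recapping targets, 5 controls and 19 nucleoporins), and the comparison of neighbouring genes were added after the data were seen. The workbook held further rows of genes beside the nucleoporins, which were only checked to repeat the deposited values and not analysed as a list.

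The text names, per line, the 8 genes farthest above and the 5 farthest below every other line, leaving out XIST, Y-linked genes and gene models without a symbol. From each list it names up to 4 members with the widest range among those reaching 5, and it names 38 further genes whatever their values, of which 3, and 1 of the 31 lists, are not reported here, although counts of lists include it. Relations between mean list scores were tested by exact permutation with Benjamini-Hochberg adjustment over 4 relations. Among genes with a mean log2 value above 3, spans over 100 kb were compared with spans under 10 kb, with 1000 bootstrap draws over genes. Of 11337 genes with a mean log2 value above 3 and a known place, 10018 were left with 1 per overlapping cluster, and windows of 15 neighbours among them were set against 1000 shuffled gene orders. Alternatives were median-of-ratios, upper-quartile and TMM scaling computed from the deposited values, pseudocounts of 0.1 and 5, no filter, genes reaching 5, gaps of 2-fold and 8-fold, the mean of the 5 others, the mean over members, spans of 50 and 20 kb, Pearson's r and each line left out.

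Steps were tested on simulated data. For UACC-812 against the 5 others, over 16418 genes, 84% of genes raised 8-fold and 88% of those lowered 8-fold were called, 100% of both at 32-fold, and 0 unchanged genes. There all lines shared the same baseline, with noise of a standard deviation of 0.4 log2 units. Only genes with higher medians were changed. Pairs of real lines differed at least 4-fold in 12.8% to 27.1% of genes, so the 0 unchanged genes called say little of real lines. An unshifted list of 30 genes lay at percentile 70.2 and one shifted by 1 log2 unit at 100. The worth of a read was recovered within 0.17% over 509 single-exon genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.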

Results

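RNA from 6 established human breast cancer cell lines, prepared with an mRNA library kit, was sequenced as single-end reads, with 1 library for each line. UACC-812 and T47D are labelled ductal carcinoma, MDA-MB-415 and SKBR3 adenocarcinoma, MDA-MB-453 metastatic carcinoma and CAL51 breast carcinoma. The series title refers to a cancer subclass that has lost transcriptional and epigenetic control and resists immunotherapy, but the labels place no line in or outside such a subclass. Each line was therefore its own group, set against the 5 others. There were no replicates, so no difference between lines carries a measure of biological error. Values are deposited RPKM summed over the exons of a gene. Sequencing depth, recovered from the steps of low values, was 25600000 reads in UACC-812, 30200000 in MDA-MB-415, 33700000 in SKBR3, 33900000 in MDA-MB-453, 29200000 in T47D and 36500000 in CAL51. A value of 3 reads in an exon of 150 bp was worth between 0.548 in CAL51 and 0.781 in UACC-812, and differences near that level were not detectable. Of 16418 genes used, between 13078 in SKBR3 and 14389 in UACC-812 exceeded a value of 1. Over all genes, the median difference from the 5 others was +0.19 log2 units in UACC-812, -0.01 in MDA-MB-415, -0.46 in SKBR3, 0 in MDA-MB-453, +0.09 in T47D and +0.23 in CAL51. Medians of gene lists, their intervals and counts of list members at least 2-fold above or below the others are given relative to these shifts. Genes with a mean log2 value above 3 were shifted by +0.18, -0.20, -0.62, +0.03, +0.13 and +0.32, in the same order of lines. Medians and counts of well expressed lists therefore lean low in SKBR3 and MDA-MB-415. Percentiles are matched on expression, so they can differ from the sign of a median.

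Receptor and lineage genes were read first, to place each line. *ESR1*, the estrogen receptor gene, stood at 284 in T47D, 166 in UACC-812 and 83 in MDA-MB-415, and at 0.0522 or lower in SKBR3, MDA-MB-453 and CAL51. *PGR*, the progesterone receptor gene, was 586 in T47D and 108 in UACC-812. *ERBB2*, which encodes the HER2 receptor, reached 49826 in UACC-812 and 25464 in SKBR3, against 1122 to 6356 in the others, and *GRB7*, its neighbour on chromosome 17, 1462 and 1106. *EGFR* was 415 in CAL51, 388 in SKBR3 and 5.65 in MDA-MB-415. The luminal transcription factor gene *GATA3* ranged from 8.28 in CAL51 to 1796 in T47D, and *FOXA1* from 16.5 in CAL51 to 294 in MDA-MB-453. *XBP1* was 34.8 in CAL51 and 387 to 846 elsewhere. *CDH1*, which encodes E-cadherin, stood at 0.823 in SKBR3 and 3978 in T47D, while *EPCAM* lay between 1329 and 3156 in all 6 lines. *VIM*, which encodes the intermediate filament vimentin, was 2810 in CAL51 and at most 28.6 elsewhere. *ZEB1*, a repressor of epithelial genes, was 91.9 in CAL51 and at most 4.47 elsewhere, and *TGFBR2*, a TGF-beta receptor gene, was 140 in CAL51 and 0.241 in UACC-812. *KRT5*, a basal keratin gene, was 244 in MDA-MB-415 and at most 10.9 elsewhere.

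**Figure D1:**
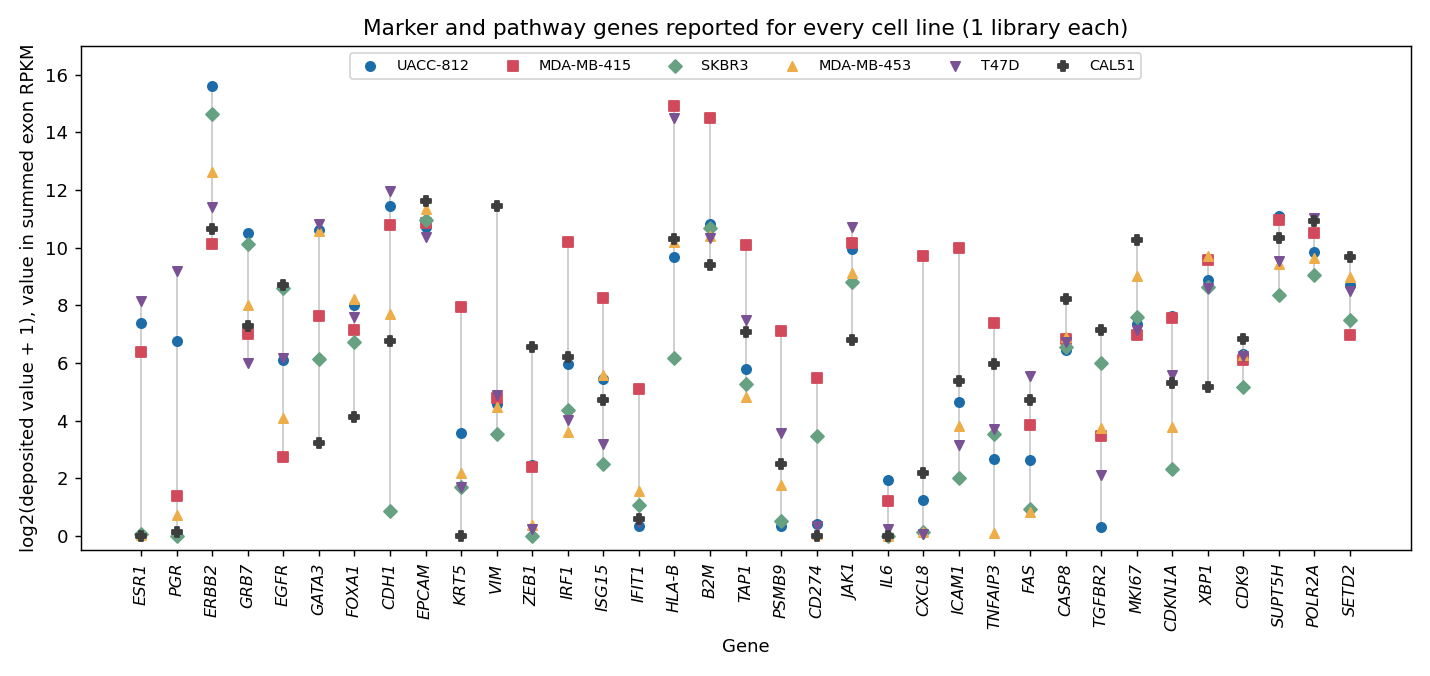
Levels of 35 genes chosen for every line, on the log2(value + 1) scale of deposited summed exon RPKM (vertical axis), with 1 symbol per cell line and a grey line over their range. *ERBB2* is highest in UACC-812 (49826) and SKBR3 (25464), *VIM* in CAL51 (2810), and *IRF1* (1160) in MDA-MB-415.

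Genes at least 4-fold beyond the nearest other line were counted next, on the log2(value + 1) scale. MDA-MB-415 had 606 genes above and 128 below every other line, and CAL51 658 above and 323 below. UACC-812 had 295 above and 31 below, T47D 137 above and 57 below, and MDA-MB-453 67 above and 157 below. SKBR3 had 87 above and 318 below as deposited, so 21.5% of its genes apart were higher, whereas after TMM scaling 180 stood above and 174 below, or 50.8% higher. TMM scaling gave 242 above and 38 below in UACC-812, 665 and 113 in MDA-MB-415, 75 and 179 in MDA-MB-453, 123 and 70 in T47D, and 530 and 397 in CAL51. Leaving a line out of the reference leaves 4 lines to pass in place of 5, so such counts can only stay or rise, and they are not like for like with those against 5. Without UACC-812, 254 genes stood above in T47D. Without MDA-MB-415, 455 stood above and 59 below in UACC-812, and 106 above in MDA-MB-453. Without SKBR3, 63 stood below in UACC-812, 230 in MDA-MB-415, 296 in MDA-MB-453 and 94 in T47D. Without MDA-MB-453, 52 stood below in UACC-812, 542 in SKBR3 and 87 in T47D, and MDA-MB-453 itself had 102 above without T47D and 107 without CAL51.

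**Figure D2:**
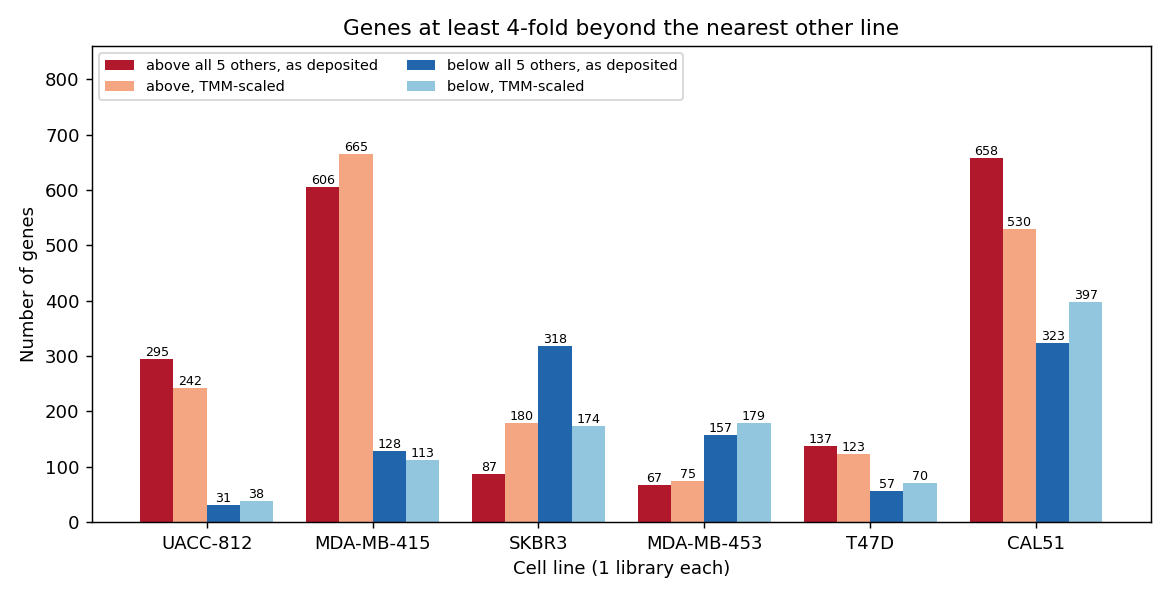
Number of genes (vertical axis) at least 4-fold above or below all 5 other lines in each cell line, as deposited (dark bars) and after TMM scaling (light bars). MDA-MB-415 and CAL51 have the most genes above the others (606 and 658), and the SKBR3 split turns from 87 above and 318 below to 180 above and 174 below.

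The position of 31 gene lists was read in each line from the median over members, placed among 10000 random lists of the same size and mean expression. A list was called outside when it lay beyond the central 95% of them, which chance alone gives for 1.55 of 31 lists per line. Members of a list vary together more than random genes do, which makes such random lists too narrow. Outside lists numbered 21 in MDA-MB-415, 14 in CAL51, 13 in MDA-MB-453, 11 in UACC-812, 9 in SKBR3 and 8 in T47D. Under each of 14 alternative settings, 13 of these lists lay outside on the same side in MDA-MB-415, 7 in CAL51, 8 in MDA-MB-453, 6 in UACC-812, 4 in SKBR3 and 4 in T47D. The 95% interval of the median over members reached 0 for 5 of the outside lists in MDA-MB-415, 4 in CAL51, 6 in MDA-MB-453, 4 in UACC-812, 2 in SKBR3 and 3 in T47D. In MDA-MB-415 these were the receptor and kinase, estrogen receptor, ERBB, mesenchymal and stromal lists. In CAL51 they were the interferon, TNF, basal and ERBB lists. For MDA-MB-453 they included MHC class II, TGF-beta, mesenchymal, ribosomal and oxidative phosphorylation lists. UACC-812 had the death receptor, mesenchymal, glycolysis and leukocyte lists among them. SKBR3 had MHC class II and TGF-beta genes, and T47D TGF-beta, mesenchymal and 17q12 genes.

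**Figure D3:**
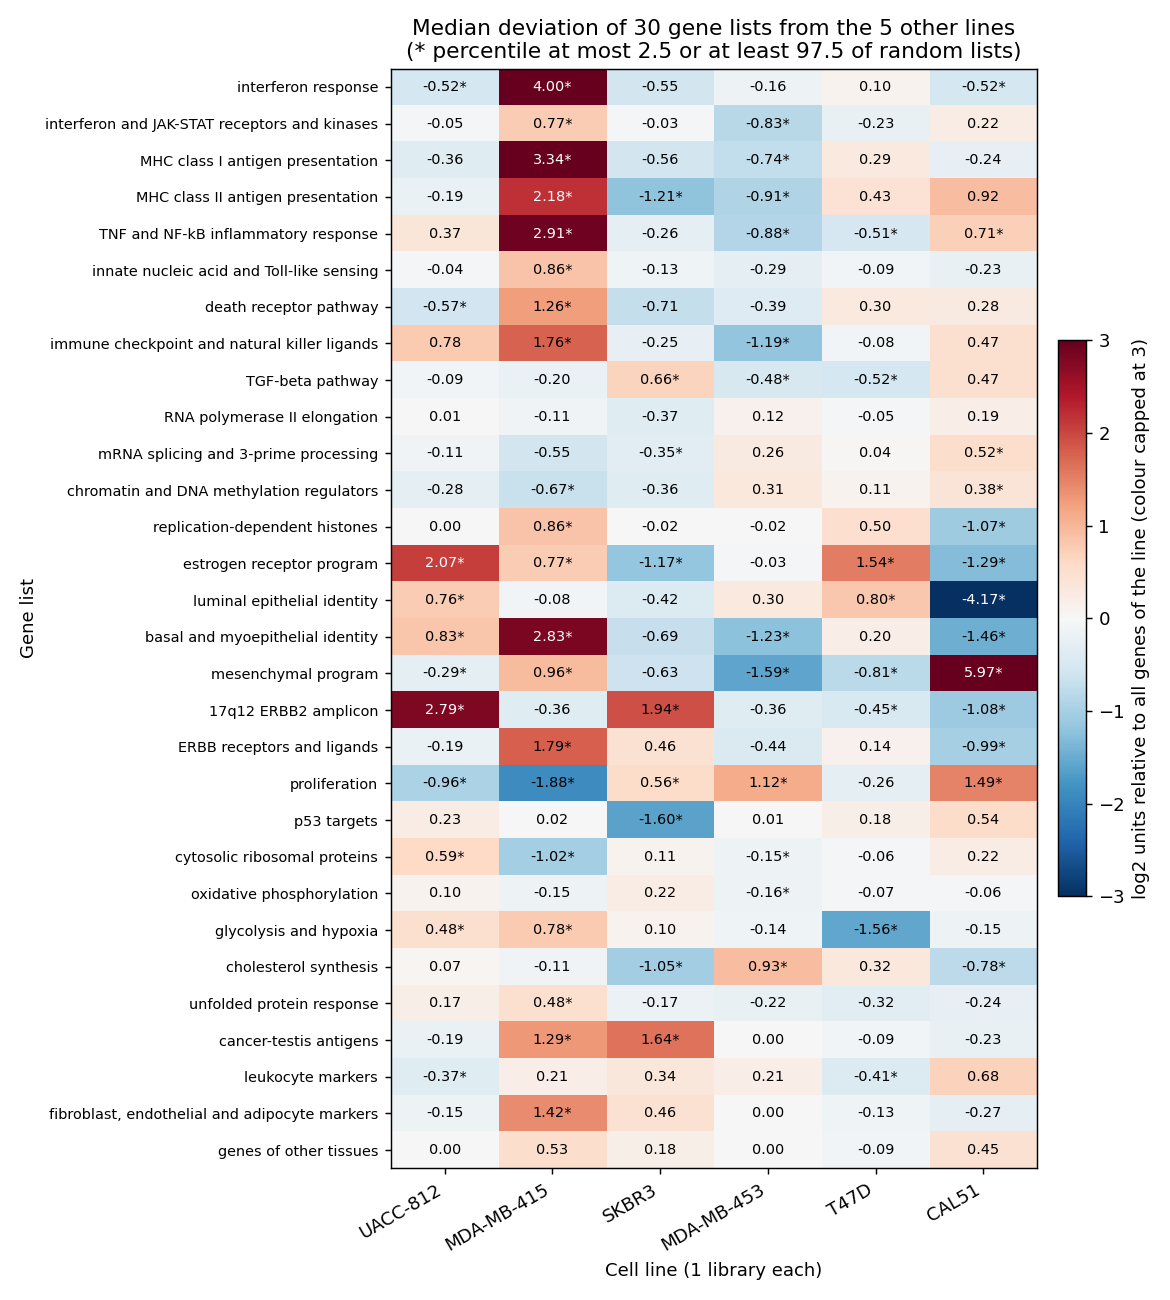
Median log2 difference of each of 30 gene lists (vertical axis) in each cell line (horizontal axis) from the median of the 5 other lines, relative to all genes of that line. Red is higher and blue lower, with colour capped at 3, an asterisk marks a list beyond the central 95% of its random lists, and the luminal and mesenchymal lists stand at -4.17 and +5.97 in CAL51.

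Immune response genes were compared because the title concerns immunotherapy. MDA-MB-415 had the highest level of 43 of the 49 measured interferon response genes, and 47 lay at least 2-fold above the median of the 5 others. The list median was +4.0 log2 units (95% interval of the median over genes 3.32 to 4.90, percentile 100). *IFI6* stood at 7428 against 3.53 to 358 elsewhere, *MX1*, an antiviral GTPase gene, at 1436 against at most 97.2, and *IFIH1*, a cytosolic sensor of double-stranded RNA, at 912 against at most 151, being listed at 0 in CAL51. The transcription factor gene *IRF1* was 1160 with a next highest value of 73.1, and *ISG15* and *IFIT1* were 305 and 33.5. *LGALS3BP* was 3076 in SKBR3 and 1782 in MDA-MB-415. The list lay below its random lists in UACC-812 (median -0.52, percentile 0.02) and CAL51 (-0.52, percentile 0.65), and inside in SKBR3 (-0.55, 5.53), MDA-MB-453 (-0.16, 31.6) and T47D (+0.10, 54.2). The CAL51 percentile was 14.4 without MDA-MB-415 in the reference, 6.03 without MDA-MB-453 and 2.69 with a pseudocount of 5. SKBR3 passed below at 1.14 without UACC-812 and 2.39 without CAL51, and T47D passed above at 99.9 without MDA-MB-415. With the mean of the 5 others as reference, SKBR3, MDA-MB-453 and T47D lay below, at 0, 1.01 and 0.09.

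Genes of MHC class I antigen presentation were highest in MDA-MB-415 for 19 of 21 members, with 20 at least 2-fold above the others (median +3.34, interval 2.00 to 4.73, percentile 100). *B2M*, which encodes the shared light chain, was 23318 there and 670 to 1810 elsewhere. The peptide transporter gene *TAP1* was 1090 against at most 178, the immunoproteasome gene *PSMB9* 138 against at most 10.9, the peptidase gene *ERAP2* 1046 against at most 122, and *NLRC5*, an activator of class I transcription, 518 against at most 73.8. *HLA-B* was 31203 in MDA-MB-415, 22970 in T47D and 70.2 in SKBR3, and *HLA-F* 1287 in MDA-MB-415 and 0.326 in SKBR3. HLA genes resemble each other closely and vary between people, so their single values are uncertain. MDA-MB-453 lay below (median -0.74, percentile 0.01). UACC-812 (-0.36, 11.2), SKBR3 (-0.56, 4.96), T47D (+0.29, 88.95) and CAL51 (-0.24, 9.48) were inside, and each passed outside under some settings. UACC-812 reached 1.68 without MDA-MB-453, SKBR3 1.07 without MDA-MB-453 and 0.46 without CAL51, and T47D 99.96 without MDA-MB-415. CAL51 reached 1.59 without UACC-812, 1.28 without SKBR3, 0.34 without MDA-MB-453, and 1.81, 1.3 and 2.43 with median-of-ratios, upper-quartile and TMM scaling.

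Of 34 measured genes of the TNF and NF-kB inflammatory response, 28 lay at least 2-fold above the others in MDA-MB-415 and 26 were highest there (median +2.91, interval 1.46 to 4.55, percentile 100). *CXCL8*, the neutrophil chemokine gene listed as *IL8*, was 828 against at most 3.58, *CCL20* 331 against at most 1.88, *IL32* 2996 against at most 728, *TNFAIP2* 784 against at most 217, *ICAM1*, an adhesion molecule gene, 1016 against at most 40.6, and *TNFAIP3*, a feedback inhibitor, 168 against at most 60.7. *IL6* was at most 2.87, in UACC-812. CAL51 lay above (+0.71, percentile 99.2) and MDA-MB-453 and T47D below (-0.88, percentile 0, and -0.51, percentile 0.02), with UACC-812 (+0.37, 88.99) and SKBR3 (-0.26, 6.92) inside. The CAL51 interval reached 0 (-0.23 to 1.83), with 14 members at least 2-fold above and 4 below. The T47D percentile was 24.1 without MDA-MB-415 in the reference and 4.82 without CAL51. That of CAL51 was 96.3 without MDA-MB-453, 97.0 without T47D, 74.8 against the mean of the 5 others and 93.4 with the mean over members. SKBR3 passed below at 0.83 without UACC-812, 0.02 without MDA-MB-453 and 0.17 without T47D, and at 1.05, 0.69 and 1.22 with median-of-ratios, upper-quartile and TMM scaling.

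The title also concerns transcription. The 43 genes of RNA polymerase II elongation were inside in all 6 lines, with medians of +0.01 in UACC-812, -0.11 in MDA-MB-415, -0.37 in SKBR3, +0.12 in MDA-MB-453, -0.05 in T47D and +0.19 in CAL51, and percentiles from 7.14 in SKBR3 to 80.98 in MDA-MB-415. *CDK9*, the kinase that releases paused polymerase, ranged from 35 in SKBR3 to 113 in CAL51, and *POLR2A*, the largest polymerase subunit gene, from 529 in SKBR3 to 2106 in T47D. *SUPT5H*, an elongation factor gene, was 330 in SKBR3 and 2214 in UACC-812, and *SETD2*, a histone methyltransferase gene, 123 in MDA-MB-415 and 814 in CAL51. *ELL2* was 944 in MDA-MB-415 against at most 133, *TCEA3* 0.821 in SKBR3 against at least 19.2, and *EAF2* 5.89 in SKBR3 and 85.3 in MDA-MB-453. *CDK12*, which lies in the *ERBB2* region, was 5385 in SKBR3 and 2047 in UACC-812. The SKBR3 list passed below at 0.35 against the mean of the 5 others, and at 0.55 without UACC-812, 0.83 without MDA-MB-415, 1.02 without MDA-MB-453 and 0.27 without CAL51 in the reference.

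Further immune lists lay above in MDA-MB-415. MHC class II genes had a median of +2.18, checkpoint and natural killer ligand genes +1.76, death receptor genes +1.26, nucleic acid and Toll-like sensing genes +0.86 and interferon and JAK-STAT receptor and kinase genes +0.77. *CD274*, which encodes the checkpoint ligand PD-L1, was 43.2 against at most 10.1, *IDO1*, a tryptophan-degrading enzyme gene, 516 against at most 15.2, *LGALS9* 356 against at most 38.3, *HLA-G* 3149 against at most 271 and *TNFSF10*, the gene of the death ligand TRAIL, 1046 against at most 67.5. *RIPK3* and *MLKL*, necroptosis genes, were 79 and 114, *NOD2* 138, *TLR6* 16.4 against at most 0.481, *IL6ST* 2240, *LIFR* 355 and *IL15RA* 72.7. Other members were highest elsewhere. *HLA-DRB1* (170), *HLA-DMB* (80.9), *CASP8* (298), *OSMR* (181.8) and *TMEM173*, the STING gene (159), were highest in CAL51, *FAS* (45.2) and *JAK1* (1700) in T47D, *MICA* (156) in UACC-812, and *C6orf150*, the cGAS gene (53.6), in MDA-MB-453. In MDA-MB-415 *CTSS* and *CD74* were 245 and 783, and *JAK1* was lowest in CAL51 at 111. With genes reaching 5, the receptor and sensing lists of MDA-MB-415 were inside, at percentiles of 96.6 and 97.0.

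MDA-MB-415 also stood apart by basal genes. The basal list had a median of +2.83 with 18 of 23 members at least 2-fold above, the ERBB receptor and ligand list +1.79, glycolysis and hypoxia +0.78 and the unfolded protein response +0.48. The interval of the ERBB list reached 0 (-0.07 to 3.58), with 8 of 13 members at least 2-fold above and 2 below. In that list the receptor genes *EGFR* (5.65) and *ERBB2* (1122) were lowest in MDA-MB-415. *KRT6A* and *KRT6B* were 1084 and 752 against at most 19 and 27.6, belonging to a family of near-identical genes and uncertain, *EGF* 582.2, *AZGP1* and *APOD* 3228 and 3352, *ADM* 424, *STARD4* 1157, *CHAC1* 75.3, *TRIB3* 267 and *CRELD2* 823. *SPARC*, a matrix glycoprotein gene, was 26924 against at most 1782, *CD44* 3111 and *TGFBI* 388. Proliferation genes lay below (-1.88, with 26 of 31 members at least 2-fold lower), with *MKI67*, a marker of cycling cells, at 125, *TYMS* at 44.7, *TOP2A* at 501 and *AURKA* at 119, as did ribosomal proteins (-1.02, 24 of 46), with *RPL30* at 744. The genes farthest above every other line were *HPGD*, a prostaglandin-degrading enzyme gene, at 16412 with 9.89 next, *CFB*, complement factor B, at 41916 with 66.7 next, *S100A7* at 1902, *SCGB2A1* at 2117 and *TRIM31* at 1797. *TRIM10* (1350), *TRIM15* (1275) and *TRIM40* (1029) were listed at 0 in all other lines. For these *TRIM* genes, reads shared with other genes of their family were not tested. The farthest below were *BLMH* (1.85, with 141 next), *DGKH* (4.96), *PTPRS* (5.10), *KCTD15* (1.90) and *GLRB*, listed at 0. Some other lists outside depended on settings. The estrogen receptor list (+0.77) was at percentiles of 93.0 without SKBR3, 56.5 without MDA-MB-453, 46.9 without CAL51 and 87.7 against the mean of the 5 others, histones (+0.86, *HIST1H2AC* 137, *HIST1H2BC* 29.3, *HIST1H2BD* 75.5) at 97.2 without UACC-812, 96.2 without CAL51, 95.8 with a pseudocount of 0.1, 97.4 with genes reaching 5 and 86.1 with the mean over members, and the mesenchymal list (+0.96) at 97.49 without UACC-812. Cancer-testis genes (+1.29, *PRAME* 101) were at 96.8 with genes reaching 5 and 96.1 against the mean of the 5 others, and chromatin regulators (-0.67, *KDM2B* 19.2) lay at 2.54 against the mean of the 5 others.

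CAL51 stood apart by mesenchymal genes. Of 26 measured members, 20 lay at least 2-fold above the others, with a median of +5.97 (interval 1.05 to 6.61, percentile 100). *CDH2*, which encodes N-cadherin, was 1084 against at most 19.6, and *FBN1*, a microfibril gene, 3358 against at most 104, whereas *CD44* was 103. Of 28 luminal genes, 24 lay at least 2-fold below, with a median of -4.17, *PRLR*, the prolactin receptor gene, at 7.10, *MUC1* at 39.4 and *TFAP2B* at 0.00606. The other 4 lay within 2-fold, among them *EPCAM*, which was highest in CAL51 at 3156. Proliferation genes were +1.49, with 24 of 31 at least 2-fold above, *MKI67* at 1242, *TYMS* at 955 and *KIF11* at 2261. The basal list (-1.46, with 12 of 23 members at least 2-fold below but 8 above, interval -2.88 to 2.39), the estrogen receptor list (-1.29), the 17q12 list (-1.08), histones (-1.07) and cholesterol synthesis (-0.78) lay below. *KRT5*, *KRT6A* and *KRT6B* were listed at 0, against *ITGA6* at 1893, and the basal percentile with the mean over members was 12.8. *HIST1H4H* was 0.0547 against at least 12.2, though histones lay at 5.64 against the mean of the 5 others. The genes farthest above were *PREX2* (2237, with 0.81 next), *COL4A2* and *COL4A1*, basement membrane collagen genes (4076 and 2566), *SPON1* (1509), *PDPN* (805), *IGF2BP1* (771), *LEFTY2* (563) and *PTPRD* (950.3). The farthest below were *GPR56* (0.02, with 424 next), *SYCP2* (1.44), *PROM2* (0.47), and *FXYD3* and *ALKBH3*, both listed at 0. Splicing genes (+0.52, *SF3A2* 752, *CPSF3* 1825) lay at 97.4 without SKBR3. Chromatin regulators (+0.38, *WHSC1* 1752, *TET1* 34.8) lay at 96.02 without UACC-812 and 91.1 without MDA-MB-415, and ERBB receptors and ligands (-0.99, with *ERBB4* at 368) at 4.26 without SKBR3 and 12.9 with the mean over members. Members of that list went both ways, 4 at least 2-fold above and 6 below (interval -2.36 to 2.44).

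UACC-812 combined estrogen receptor genes with the *ERBB2* region. The estrogen receptor list had a median of +2.07 and the luminal list +0.76, with *SCUBE2* at 2607 against at most 618. The 17q12 list, genes around *ERBB2*, was +2.79, with 17 of 18 members at least 2-fold above and *THRA* at 488 against at most 104, although *PPP1R1B* was 0.911. *RPL19* and *RPL23*, ribosomal protein genes that lie near *ERBB2*, were 48046 and 39270, and the ribosomal list was +0.59. *COX6C*, *UQCRB*, *ATP5D* and *NDUFA1*, respiratory chain genes, were highest here at 4013, 1741, 639 and 558, with their list inside (+0.10, percentile 92.02). Proliferation genes lay below (-0.96). *TFF1* and *TFF3*, estrogen-responsive secreted peptide genes, were 2737 and 812 with 8.34 and 15.4 next. *SLIT1* (340), *AP3B2* (126), *UPK3A* (268) and *KL* (49.7) followed, as did *PEG3* (326) and *ZIM2* (274), which share exons and are uncertain. Farthest below were *PLS3* (4.33, with 388 next), *STAT6*, a signal transducer of interleukin-4 (4.08, with 135 next), *PDGFC* (0.07), and *SPAG16* and *TNIK*, both listed at 0. Other lists outside depended on settings. Basal genes (+0.83) lay at 93.2 without SKBR3, 63.1 without MDA-MB-453, 92.9 against the mean of the 5 others and 92.2 with the mean over members. Glycolysis (+0.48, 5 members at least 2-fold above and 5 below) lay at 90.97 without T47D, at 90.1, 91.8 and 87.3 with median-of-ratios, upper-quartile and TMM scaling and at 81.0 with the mean over members. Death receptor genes (-0.57) lay at 6.96 without MDA-MB-415, 4.11 without T47D, 11.6 without CAL51 and 2.97 with a pseudocount of 5, and leukocyte markers (-0.37) at 2.81 without SKBR3. Mesenchymal genes (-0.29, 9 members at least 2-fold above and 10 below) lay at 4.12 without CAL51, at 4.39 and 4.84 with median-of-ratios and TMM scaling and at 6.25 with the mean over members.

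T47D shared the estrogen receptor list, with a median of +1.54, and the luminal list, with +0.80. *GREB1*, an estrogen-responsive gene, was 3185 against at most 356, *STC2* 2160 against at most 1140, *PRLR* 12847 against at most 610 and *CXCL12*, a chemokine gene, 1235 against at most 8.45. *PIP*, a secreted apocrine protein gene, was 911, *TP53I3* 1686 against at most 116, and *GAGE1*, a near-identical copy of its family and uncertain, 803. Glycolysis and hypoxia genes lay below (-1.56, with 19 of 29 members at least 2-fold lower), *LDHB* at 50.2 and *EGLN3* at 4.16, and so did TGF-beta genes (-0.52). Of the TGF-beta members, 4 lay at least 2-fold above and 8 below (interval -1.27 to 0.11). The genes farthest above were *PPP4R4* (633), *SERPINA6* (358), *CXCL12*, *ODZ3* (1890) and *CT45A1*, *CT45A3*, *CT45A4* and *CT45A6* at 120, 131, 180 and 96.6, which are near-identical copies and uncertain. Farthest below were *RPS6KA3* (0.39, with 248 next), *FAT1* (2.74, with 575 next), *TES* (0.39), *FZD6* (0.04) and *SNX7*, listed at 0. Mesenchymal genes (-0.81) lay at a percentile of 32.6 without CAL51, the 17q12 list (-0.45) at 13.4 without UACC-812 and 26.8 without SKBR3, and leukocyte markers (-0.41) at 6.18 without MDA-MB-453. Mesenchymal members went both ways, 7 at least 2-fold above and 13 below (interval -2.24 to 0.88).

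MDA-MB-453 had higher proliferation and cholesterol synthesis genes, with medians of +1.12 and +0.93 and 19 of 31 and 11 of 24 members at least 2-fold above. Mesenchymal genes (-1.59), basal genes (-1.23), checkpoint and natural killer ligands (-1.19) and interferon and JAK-STAT receptors and kinases (-0.83) lay below. Mesenchymal members went both ways, 7 at least 2-fold above and 14 below (interval -2.47 to 0.91). *CD44* was 0.46 against at least 36, *LAMA3* was listed at 0, *MUC1* was 1.28 against at least 12.9, *IL6ST* 42.7 against at least 241 and *ENO2* 724. *CLCA2* was 6153 against at most 331 and *BMP4* 129. The genes farthest above were *SLC1A7* (886, with 1.41 next), *PPAPDC1A* (219), *GUCY1A3* (277), *ANKRD30A*, a breast differentiation antigen gene (7309, with 92.4 next), *SMC1B* (741), *CALML5* (58.6), *SLCO2A1* (276) and *PRG2* (683). Farthest below were *GSTM3*, a glutathione transferase gene (2.16, with 1131 next), *CD109* (0.05), *FAM135A* (0.01), and *IFT57* and *GLDC*, both listed at 0. MHC class II genes (-0.91) lay at percentiles of 10.1 without MDA-MB-415, 3.52 without T47D, 3.95 without CAL51, 3.60 with a pseudocount of 0.1, 3.67 with genes reaching 5, 4.22 against the mean of the 5 others and 21.8 with the mean over members. TGF-beta genes (-0.48, 6 members at least 2-fold above and 7 below) lay at 10.4 without MDA-MB-415, 2.85 without SKBR3, 7.57 without CAL51, 3.46 and 2.79 with median-of-ratios and TMM scaling and 12.9 with a pseudocount of 5, and turned to 61.99 with the mean over members. Ribosomal proteins (-0.15) lay at 31.8 without UACC-812, 19.2 without CAL51, 3.38 and 3.37 with upper-quartile and TMM scaling, 3.40 against the mean of the 5 others and 3.81 with the mean over members. Oxidative phosphorylation (-0.16) lay at 2.75 without UACC-812, 6.58 without MDA-MB-415, 3.82 without SKBR3, 3.58 without CAL51, 7.70, 5.66 and 6.71 with median-of-ratios, upper-quartile and TMM scaling and 3.97 with the mean over members.

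SKBR3 shared the 17q12 list with UACC-812, at a median of +1.94, with *GSDMB* at 1911. The cancer-testis list was +1.64, with *CTAG2* at 232 against at most 2.99 and *MAGEA3*, which has a near-identical copy and is uncertain, at 47.3. Below lay p53 targets (-1.60, with 18 of 28 members at least 2-fold lower), estrogen receptor genes (-1.17, at a percentile of 3.55 with a pseudocount of 5), MHC class II genes (-1.21) and cholesterol synthesis (-1.05). *CDKN1A*, the gene of the cell cycle inhibitor p21, was 3.95 against at least 12.8, *GDF15* 0.0666, *MVD*, a mevalonate pathway gene, 5.22 against at least 64.8, *PMVK* 24.4 and *TM7SF2* 22.9. *SPATA18* was listed at 0, and *ABCA12* was 1207 here and 2446 in MDA-MB-453. Farthest above were *TDRD1*, a germline gene (1292, with 1.43 next), *DHRS2* (6626, with 30.7 next), *H19*, an imprinted noncoding RNA (2057, with 21.3 next), *TEKT4* (72.4), *SIGLEC6* (114), *WBSCR17* (57.1) and *KRT78* (1553). Farthest below were *LAMC1* (1.5, with 531 next), *BDH1* (0.11), *SMARCA2*, a chromatin remodelling ATPase gene (4.22, with 432 next), *ITGA6* (1.84) and *OPLAH*, listed at 0. TMM scaling left each of these genes at least 4-fold apart. Proliferation genes (+0.56, *TOP2A* 10007, *AURKA* 3360) lay at percentiles of 61.4 without UACC-812, 69.97 without MDA-MB-415 and 97.4 against the mean of the 5 others, TGF-beta genes (+0.66, 10 members at least 2-fold above and 7 below, *BMP7* 149) at 96.5 without T47D and 97.2 against that mean, and MHC class II genes at 2.68 without MDA-MB-415. Splicing genes (-0.35, *CPSF1* 146, *SFRS3* 4568) lay inside without any 1 of the others, at 3.29 without UACC-812, 3.54 without MDA-MB-415, 8.71 without MDA-MB-453, 5.09 without T47D and 8.1 without CAL51, and stayed below under only 2 of the 14 alternatives.

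Markers of other cell types were mixed. The 21 measured leukocyte markers were inside in MDA-MB-415 (+0.21, percentile 67.2), SKBR3 (+0.34, 67.6), MDA-MB-453 (+0.21, 97.4) and CAL51 (+0.68, 97.2). In MDA-MB-415, beside its higher immune lists, *CD14*, *ITGAM* and *LCP1* were 176, 149.7 and 2488, and *HBB* was listed at 0. The 16 measured genes of other tissues were inside in all lines, with medians from -0.09 in T47D to +0.53 in MDA-MB-415. *LIN28A*, a pluripotency gene, was 55.8 in T47D and 60.5 in CAL51, *MAP2* 123 in T47D, and *TNNT2* and *SYP* 125 and 39 in UACC-812. Of stromal markers 10 of 20 were measured. They lay above in MDA-MB-415 (+1.42, interval -0.86 to 3.60, percentile 99.02, with 6 members at least 2-fold above), at 92.05 with genes reaching 5 and 93.89 with the mean over members, and inside in the 5 others. *VWF* was 20.4 in MDA-MB-415, *PDGFRB* 188 in CAL51, *COL1A1* 213 in T47D and *PLIN1* 24.9 in UACC-812. *RPS21* ranged from 3460 in MDA-MB-415 to 35094 in SKBR3.

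The lines were compared in pairs for overall similarity. Across genes, which are not independent replicates, Spearman's rho was highest between UACC-812 and T47D (0.898) and between MDA-MB-453 and T47D (0.897), and lowest between MDA-MB-415 and CAL51 (0.762). Genes at least 4-fold different numbered 2097 between UACC-812 and T47D and 4455 between MDA-MB-415 and CAL51. CAL51 reached at most 0.837 with any line, and SKBR3 was closest to MDA-MB-453 (0.891). With genes reaching 5, and with Pearson's r on log2 values, the highest pair was MDA-MB-453 and T47D.

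Relations between list scores over the 6 lines were tested by exact two-sided permutation of all 720 orders, whose smallest p is 0.0028, in a family of 4. Interferon and MHC class I scores rose together, with Pearson's r = 0.963 (exact permutation p = 0.0083, adjusted 0.0333) and Spearman's rho = 0.943 (exact permutation p = 0.0167, adjusted 0.0667). Without MDA-MB-415 and SKBR3, the lines farthest from the median, r was 0.901. The adjusted exact p of r was 0.144 with median-of-ratios, 0.0778 with upper-quartile and 0.133 with TMM scaling. With 1 line left out, r stayed between 0.953 and 0.986. The smallest exact p is then 0.0167, or 0.0667 adjusted for a relation that passes alone, so that alone it could not pass 0.05, and the adjusted exact p was 0.133 without UACC-812, 0.2 without MDA-MB-415, SKBR3 or T47D, and 0.0667 without MDA-MB-453 or CAL51. Interferon and TNF scores had r = 0.886 (exact permutation p = 0.147, adjusted 0.278) and rho = 0.486 (exact permutation p = 0.356, adjusted 0.711), with r = 0.14 without MDA-MB-415, 0.87 without SKBR3 and -0.26 without both, so that r rested on MDA-MB-415. Luminal and mesenchymal scores had r = -0.735 (exact permutation p = 0.208, adjusted 0.278) and rho = -0.257 (exact permutation p = 0.658, adjusted 0.878), with r = 0.229 without CAL51, -0.823 without SKBR3 and 0.218 without both, so that r rested on CAL51. Interferon and elongation scores had r = 0.175 (exact permutation p = 0.869, adjusted 0.869) and rho = 0.0857 (exact permutation p = 0.919, adjusted 0.919). That r was -0.302 without MDA-MB-415 and SKBR3, 0.7 without MDA-MB-415 alone and -0.667 without SKBR3 alone.

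Genes of long and short genomic span were compared, since the title concerns transcription as a whole. Between 2065 genes spanning over 100 kb and 2201 under 10 kb, the median difference (long minus short) was -0.48 log2 units in UACC-812 (95% bootstrap interval over genes -0.56 to -0.41), -0.15 in MDA-MB-415 (-0.24 to -0.08), +0.41 in SKBR3 (0.31 to 0.48) and +0.30 in CAL51 (0.21 to 0.38). It was +0.05 in MDA-MB-453 (-0.01 to 0.12) and +0.04 in T47D (-0.03 to 0.09). Without UACC-812 in the reference, the values of MDA-MB-415, MDA-MB-453 and T47D were -0.27, -0.07 and -0.09, and without SKBR3 those of MDA-MB-453 and T47D were 0.12 and 0.10. The intervals describe the genes of these libraries, not the spread between cultures.

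Neighbouring expressed genes were compared in windows of 15, a step chosen after the gene values had been seen, and the genes named here were chosen after that too. UACC-812 had its highest window on chromosome 17, from *STARD3* to *RARA*, with a median of +3.47 relative to all genes, against at most +1.95 in 1000 shuffled gene orders. In it *CASC3* and *WIPF2* lay at +4.29 and +4.19. In SKBR3 *GSDMB* in this window lay at +5.46 and *CDK12* just before it at +3.86, while *LASP1* and *PCGF2*, farther out, lay at -2.77 and -3.13. The lowest window in SKBR3 lay on chromosome 19, from *ZNF85* to *ZNF254*, with a median of -4.24 against -2.58 in the lowest shuffle. There *ZNF431* was 0.132 with a median of 54.8 in the others, *ZNF91* 0.352 with 41.1 and *ZNF43* 0.104 with 31.4. These zinc finger genes resemble each other in sequence, so their single values are uncertain.

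**Figure D4:**
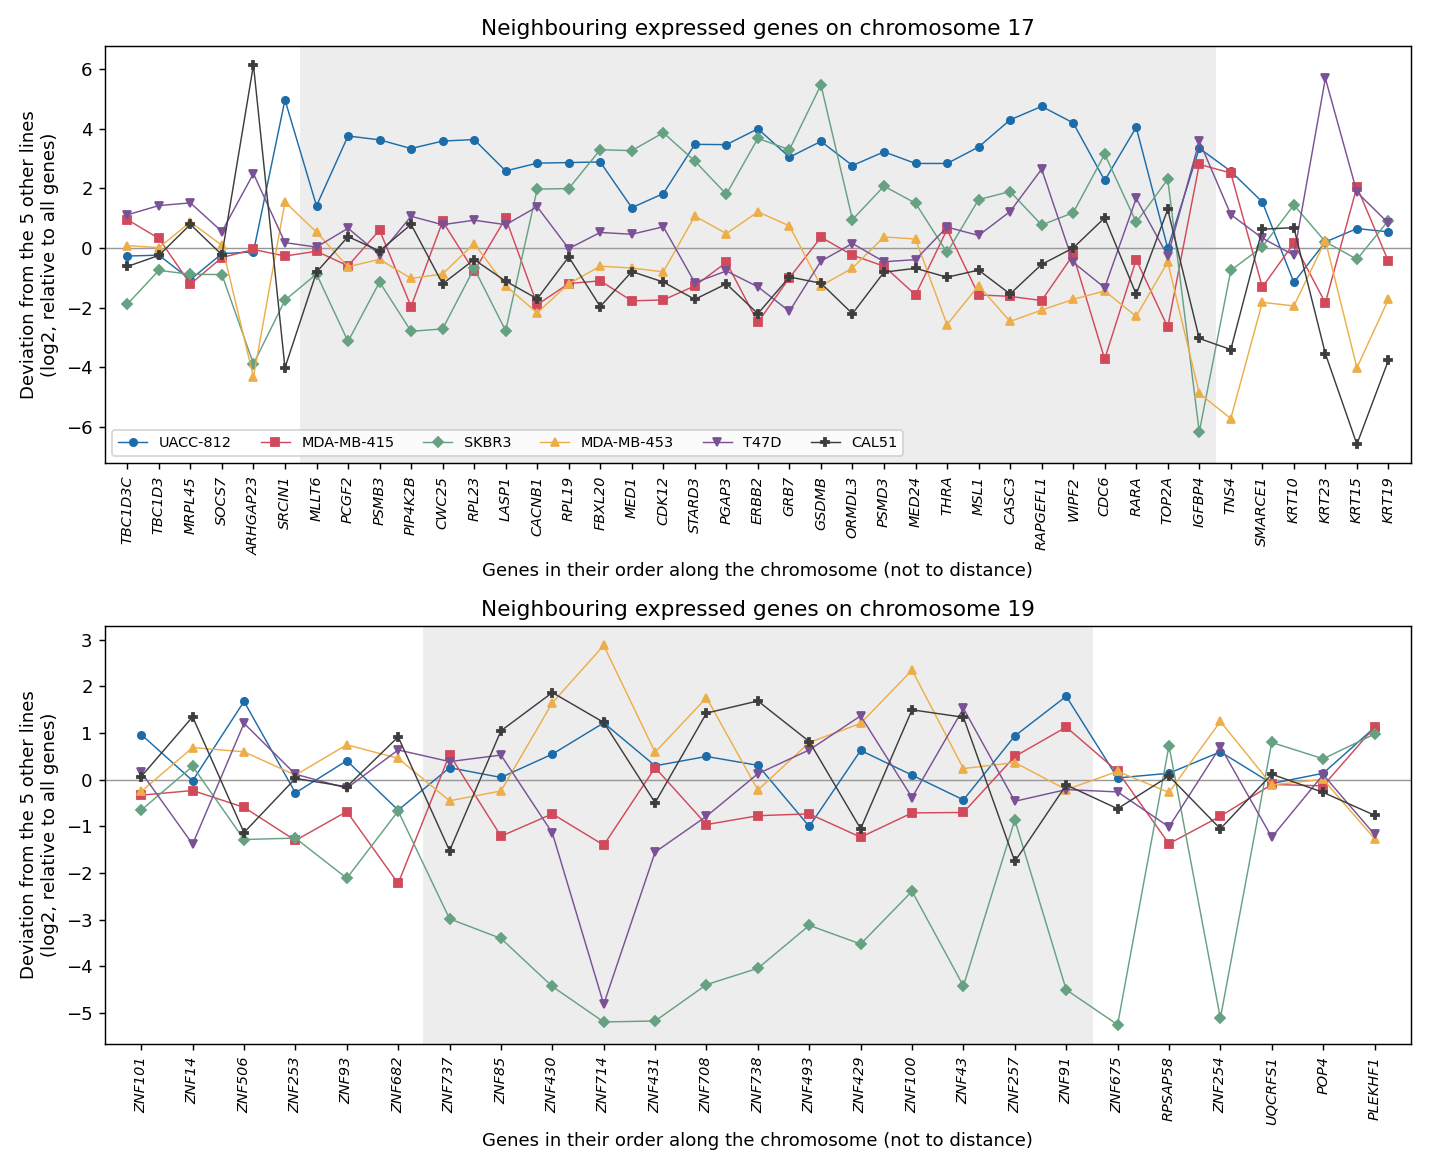
Deviation of neighbouring expressed genes from the 5 other lines (vertical axis, log2 relative to all genes of the line) in their order along chromosomes 17 and 19 (horizontal axis), with 1 coloured line per cell line and grey shading over the genes at the centres of the windows that reach 60% of the extreme window. UACC-812 is high over most of the shaded stretch of chromosome 17 (window median +3.47), and SKBR3 is low over that of chromosome 19 (-4.24).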

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

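The authors' short lists and the comparison of neighbouring genes were added only after the data were seen. No paired analysis was possible because each line has 1 library and the labels give no shared replicate. Using no filter moved nothing, since every gene in the table reached 1 in some line. Depth limits values near those of 3 reads in an exon. For calls that ended or appeared the cause was not tested, except that with 1 line left out of a relation the smallest exact p is 0.0167, or 0.0667 adjusted for a relation that passes alone.

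Counts of genes apart moved with the size of the gap. With a 2-fold gap, genes above and below numbered 959 and 156 in UACC-812, 1124 and 543 in MDA-MB-415, 271 and 1463 in SKBR3, 293 and 409 in MDA-MB-453, 483 and 169 in T47D, and 1460 and 687 in CAL51. With an 8-fold gap they were 111 and 14 in UACC-812, 354 and 42 in MDA-MB-415, 34 and 109 in SKBR3, 28 and 75 in MDA-MB-453, 59 and 27 in T47D, and 334 and 178 in CAL51.

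With a pseudocount of 0.1, 449 genes stood above and 71 below in UACC-812, 207 below in MDA-MB-415, 574 below in SKBR3, 112 above and 307 below in MDA-MB-453, 243 above and 120 below in T47D, and 631 below in CAL51. The SKBR3 percentiles were then 1.3 for interferon and 0.87 for TNF genes. With a pseudocount of 5, 173 stood above and 13 below in UACC-812, 68 below in MDA-MB-415, 56 above and 162 below in SKBR3, 81 below in MDA-MB-453, 76 above and 20 below in T47D, and 425 above and 170 below in CAL51. The CAL51 interferon percentile was then 2.69, SKBR3 had 3 lists below, and long minus short genes was 0.23 in SKBR3 and -0.36 in UACC-812.

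In SKBR3, genes above and below numbered 180 and 174 with TMM, 168 and 184 with median-of-ratios and 152 and 193 with upper-quartile scaling. In the same order, SKBR3 TNF percentiles were 1.22, 1.05 and 0.69 and CAL51 MHC class I percentiles 2.43, 1.81 and 1.3. The interferon and MHC class I relation had r of 0.974, 0.973 and 0.971, with adjusted exact p of 0.133, 0.144 and 0.0778.

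Against the mean of the 5 others, interferon percentiles were 0 in SKBR3, 1.01 in MDA-MB-453 and 0.09 in T47D, where the median turned to -0.40. MHC class I percentiles were 0.47 in SKBR3 and 0.17 in CAL51, TNF 0.36 in SKBR3 and 74.81 in CAL51, and elongation 0.35 in SKBR3. Cancer-testis genes of MDA-MB-453 turned to 0.01. Lists above numbered 5 in MDA-MB-453, 2 in SKBR3 and 4 in T47D, and lists below 9 in SKBR3 and 11 in T47D. With the mean over members, MHC class I percentiles were 2.22 in CAL51, 0 in SKBR3 and 99.93 in T47D, interferon 1.51 in SKBR3, TNF 93.4 in CAL51, and TGF-beta of MDA-MB-453 turned to 61.99. SKBR3 then had 9 lists below and T47D 5 above.

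Spans over 50 kb against under 20 kb gave 0.20 in CAL51 and -0.40 in UACC-812. The highest and lowest similarity of pairs were 0.892 and 0.749 with Pearson's r, and 0.881 and 0.719 with genes reaching 5.

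With each line left out in turn, 4 lines were left to pass, so genes apart could only stay or rise in number. Genes above ranged from 325 to 455 in UACC-812, 86 to 107 in MDA-MB-453 and 151 to 254 in T47D. Genes below ranged from 45 to 63 in UACC-812, 151 to 230 in MDA-MB-415, 356 to 542 in SKBR3, 178 to 296 in MDA-MB-453 and 73 to 94 in T47D. Lists below ranged from 4 to 8 in UACC-812 and 5 to 9 in SKBR3, and lists above from 3 to 6 in T47D and 5 to 9 in CAL51. Interferon percentiles ranged from 1.14 to 70.03 in SKBR3, 8.59 to 99.88 in T47D and 0.01 to 14.43 in CAL51. MHC class I percentiles ranged from 1.68 to 78.44 in UACC-812, 0.46 to 15.27 in SKBR3, 79.61 to 99.96 in T47D and 0.34 to 53.56 in CAL51. TNF percentiles ranged from 0.02 to 50.93 in SKBR3, 0 to 24.12 in T47D and 96.29 to 99.95 in CAL51, and elongation from 0.27 to 4.57 in SKBR3. Cancer-testis genes of MDA-MB-453 ranged from 0.43 to 86.51, at 1.95 without T47D and 0.68 without CAL51, and the estrogen receptor list of MDA-MB-415 from 46.94 to 99.94. The interferon and MHC class I r ranged from 0.953 to 0.986. Long minus short genes ranged from -0.27 to -0.11 in MDA-MB-415, -0.07 to 0.12 in MDA-MB-453, -0.09 to 0.10 in T47D and 0.23 to 0.39 in CAL51.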

Other observations

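Tests of gene order, of SKBR3 depth and exon number, and of the library-wide explanation for chromosome 19, and all tests on central genes alone, were chosen only after the result was seen.

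The authors' short lists were chosen in this study, so they are not independent evidence of their direction. The 19 nucleoporin genes lay below their random lists in UACC-812 (median -1.17, percentile 0) and MDA-MB-415 (-0.94, percentile 0.59), and above in SKBR3 (+0.62, 97.9), MDA-MB-453 (+0.55, 98.8) and CAL51 (+0.58, 99.02), with T47D inside (-0.09, 27.3). *NUP133*, a nuclear pore scaffold gene, was 450 in UACC-812 and 2952 in MDA-MB-453, *NUP188* 342 in MDA-MB-415 and 2021 in T47D, *NUP85* 309 in MDA-MB-415 and 2331 in MDA-MB-453, and *NUP93* 379 in UACC-812 and 2401 in CAL51. The MDA-MB-415 percentile was 2.51 without SKBR3 and 2.6 without CAL51. Those of SKBR3, MDA-MB-453 and CAL51 were 95.9, 78.7 and 97.1 without UACC-812, and 96.9, 81.8 and 95.9 without MDA-MB-415, and that of CAL51 was 96.7 against the mean of the 5 others. Proliferation genes had the same sign as nucleoporins in each line, at -0.96 in UACC-812, -1.88 in MDA-MB-415, +0.56 in SKBR3, +1.12 in MDA-MB-453, -0.26 in T47D and +1.49 in CAL51. The nucleoporin pattern is therefore not particular to them. *NUP85* also lies in a stretch of chromosome 17 that was high in MDA-MB-453. The 11 recapping targets were inside in all 6 lines, with percentiles from 16.8 in SKBR3 to 77.4 in CAL51, and *STAT3* was 394 in MDA-MB-453 and 3433 in MDA-MB-415, *ILF2* 3630, *VDAC3* 2423 and *EXOSC2* 497 in CAL51. The 5 control genes lay below in SKBR3 (-1.24, percentile 0.93), with *STRN4* at 119, *LMNB2* at 72.8, *BOP1* at 178 and *ACOT7* at 192, and were inside elsewhere.

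Other stretches of neighbouring genes passed all 1000 shuffled orders, with genes named after their values were seen. On chromosome 11 MDA-MB-415 had a window median of +3.02, with *CTTN*, an actin regulator gene, at 45500 against a median of 3684 in the others, *ANO1* at 5511 against 215 and *CCND1*, the cyclin D1 gene, at 1627 against 455. On chromosome 8 SKBR3 had +3.21, with *ATAD2* at 10830 against 1470 and *TMEM65* at 4387 against 172, and a second window of +2.28. CAL51 lay low over keratin genes of chromosome 17 (-3.63), with *KRT19* at 1098 against 12640 and *KRT14* listed at 0, and high over zinc finger genes of chromosome 19 (+2.35), with *ZNF560* at 974.6 against 0.953. Smaller windows were +2.16 and +2.12 on chromosomes 13 and 20 in UACC-812, +2.23 on chromosome 17 in SKBR3, +1.96 and +1.83 on chromosomes X and 17 in MDA-MB-453, -1.90 on chromosome 16 in T47D and -2.18 on chromosome 3 in MDA-MB-415. The T47D window centred on *MT1* genes, from *MT1E* to *MT1X*, which belong to the same family and are uncertain. *NUP93* beside them was 676.5 against 832.1. No copy number was measured.

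MDA-MB-415 had a high window on chromosome 6 (median +2.82), around HLA and TRIM genes, and 0 of 1000 shuffled orders gave one as high, which argues against a chance order of genes. Over all 23 genes of the windows, those with names not starting with HLA, TRIM, MIC or OR had a median of 0.30 (95% interval -0.18 to 0.98, n = 14). The genes outside immune lists had the same 0.30. Only 2 of these 14 were among the 9 central genes, the others being flanking genes that the width of the windows adds, so 0.30 says little of the stretch itself. A median under 1 had been set beforehand as favouring both explanations below, and 0.30 met it, but this was set aside for that reason after the result was seen. Those 2, *HCG4P6* (5.33) and *PPP1R11* (2.40), had a median of 3.87 in both tests, too few to decide and picked for being high. *HCG4P6* was kept by its name alone, and whether it shares reads with other genes was not tested. Reads shared by overlapping or paralogous genes and induction of immune genes that lie there therefore stay open and cannot be told apart.

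SKBR3 had lower values library-wide, with a total 76.4% of the mean of the 5 others. SKBR3 did not have the fewest reads, since 3 libraries had fewer. This cannot decide on depth as a cause, because values read as RPKM are already divided by the number of reads. Without the 100 highest genes the total was 76.5%. This cannot decide whether a few genes took most of the signal, because values of the other genes would then be low too. The 10 highest genes held 6.3% of the SKBR3 total, against 4.4% to 8.9% in the other lines. The 241 single-exon genes had a median of -0.28 (95% interval -0.54 to -0.11), and genes of 2 to 4, 5 to 16 and 17 or more exons lay lower, at -0.51, -0.66 and -0.60. These values cannot decide on loss of coverage in genes of many exons, because single-exon genes can also move alone. In MDA-MB-415 they lay at -0.78 (-0.93 to -0.62), against -0.09, -0.14 and -0.26 for the other exon classes in the same order. Loss of coverage therefore stays open. Reads not assigned to exons were not tested and stay open. The design gives no biological group for this difference, so no biological explanation was tested.

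SKBR3 had a low stretch of zinc finger genes on chromosome 19, and 0 of 1000 shuffled orders gave a window as low, which argues against a chance order of genes. Over all 27 genes of the windows the median was -2.85 (95% interval -4.85 to -1.11), but these include flanking genes that the width of the windows adds. The lower values of the whole SKBR3 library are argued against as the whole cause, since with that library's median taken off the window still lay at -4.24, against -2.58 in the lowest shuffled order. Of those 27 genes 10, or 37%, reached 5 in SKBR3, a share set beforehand as counting against loss of the segment, but all 10 were flanking genes, so this was set aside after the result was seen and decides nothing about loss of the low segment. Over the 13 central genes alone the median was -4.50 (interval -4.96 to -3.44) and 0% reached 5, but these were picked for being low, so loss of the segment stays open. *ZNF675* and *ZNF254* beyond them were low too (-5.25 and -5.11), with *RPSAP58* between them at +0.73.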
